A study of Mus musculus with 6 samples.

How the data were processed

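Messenger RNA was measured by RNA-seq in 6 libraries of CD8-negative dendritic cells from the spleens of C57BL/6 mice, 3 from CpG-pretreated and 3 from untreated animals as the labels divide them. Per the labels' protocols, dendritic cells were enriched from spleen, stained with antibodies, sorted by flow cytometry and lysed without culture, RNA was prepared with a QIAGEN RNeasy kit, and libraries of polyadenylated RNA followed a standard Illumina protocol. The series design text calls the 3 samples of each group biological replicates, and whether each came from 1 mouse or from a pool is not given in the sources used here. The p-values measure the spread between these samples only. The CpG sequence, dose, route and time before collection are likewise not given in the sources used here.

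The deposited values are whole-number read counts per Entrez gene ID for 27179 genes. Per the submitters' processing notes, CASAVA and featureCounts were used with the mm10 build, without versions. The aligner, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Reads from a gene and an overlapping antisense partner therefore cannot be told apart, and counts of near-identical genes (the globins, Iigp1, Apol11b, the Cd209, Ly6, H2-Q, H2-T and Ifi200 families) are uncertain as to which copy they belong to. The counts deposited for each of the 6 samples equalled those in the table of the whole series. Gene symbols and positions came from the RefSeq annotation of GRCm38.p6, the assembly that mm10 names, matched by gene ID. Of the IDs, 25275 matched and 1904 did not, and the unmatched ones held 0.327% of the counts.

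Total counts lay between 7855500 and 8228140 per library, so that 1 count corresponded to 0.123 to 0.127 CPM. Within each group no pair of libraries agreed within sampling noise, with chi-square values per degree of freedom of 3.30 to 20.9. All 6 libraries were therefore used as separate replicates.

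Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15, which left 11602 genes. TMM normalization, robust dispersion estimates and the quasi-likelihood F test gave log2 fold changes of CpG-pretreated over untreated, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05. Standard errors were derived from the fold change and its F statistic. CPM values use the TMM-normalized library sizes and are given as mean ± SD with n = 3 per group. The test on 3 against 3 libraries was two-sided.

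Both groups carry the replicate numbers 2, 3 and 4, and the labels do not say what a number marks. Deviations from the group mean of log2 CPM were correlated across genes between same-numbered libraries, at 0.48 for number 2, 0.25 for number 3 and 0.31 for number 4, while differently numbered libraries gave -0.39 to 0.07. Deviations cancel within a group, so positive same-numbered values push the other values down, and those add no separate support. For the same reason, a shared effect in the number 2 libraries alone would make the values among numbers 3 and 4 positive on average. Those were 0.25 and 0.31 for equal and 0.07 and 0.03 for unequal numbers. Numbers 3 and 4 are therefore not independent support for the pairing. Both libraries numbered 2 also shared a trend with gene length (Spearman correlations of -0.67 in untreated 2 and -0.55 in CpG-pretreated 2). Each same-numbered value was over 0.1, the minimum set before the data were examined, so the numbers were taken to pair the samples, on the strength of the data alone. The comparison without the number remained the principal one, as fixed beforehand. The fit with the replicate number as a block is given beside a result where it changes a call or moves a count by over 1.5 times.

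Before the data were examined, 47 gene lists were written, of pathways and of cell types that spleen could contribute. The 44 lists with at least 5 tested members were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Camera compares a list with the other genes. Member counts are given from the gene test over all genes and adjusted over the list alone. A list is described singly if it was called with or without the block, if a member was called, or if it was that of Toll-like receptors, which makes 28 lists. This choice of the lists to describe was made after the results were seen.

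Genes were named by a rule fixed before the data were examined. It takes the 8 called genes with the largest rises and the 8 with the largest falls among genes with an average log2 CPM of at least 3 and groups that do not overlap. Genes without an official symbol, Gm-numbered, Rik-named and LOC genes, pseudogenes and immunoglobulin or T cell receptor segments were left out of that part. For each described list it takes up to 4 called members with the smallest adjusted p, and, in lists with fewer than 2 of these, the 2 members with the highest average log2 CPM. It also takes Tlr9, Cd8a, Itgax, Sirpa, Xcr1 and Flt3 whatever their result. Only genes passing the filter have a fold change, and genes named outside the rule are marked as chosen after their values were seen. Some genes that the rule takes are not reported here.

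Alternatives fixed beforehand were other normalizations (DESeq2 size factors, library size only, upper quartile), no filter on low counts or at least 1 CPM in at least 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom, a non-robust fit, a test against a 1.5-fold change, the replicate block, leaving out each library in turn, and leaving out immunoglobulin, T cell receptor and haemoglobin genes. For the lists they were an estimated correlation, the fry rotation test, the block, and leaving out genes shared between lists. Blocked fits with DESeq2 and limma-voom, blocked fits without 1 pair, the block with an estimated correlation or fry and a covariate for erythroid signal were added after the data were seen.

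The gene and list tests were checked on simulated counts made from the real means and library sizes of this comparison, with 200 changed genes among 11518 tested. Without the block, 19.4% of genes changed 1.5-fold were recovered, 100% of those changed 2-fold and 100% of those changed 4-fold, with 0 unchanged genes called. With the block, 76.1% of genes changed 1.5-fold were recovered and 6 unchanged genes were called. The simulated changes were equal in every pair and fell only on more abundant genes. Spread came from the fit with the block, with a log2 SD of 0.157 between pairs. On these counts camera called a list of raised genes (adjusted p = 1.58e-46) and 0 of 20 random lists. Genes were simulated independently of one another, so this does not check the preset correlation on real lists. In the real data changes over 2-fold also went uncalled, such as Xcr1 (log2 fold change 1.27, edgeR adjusted p = 0.185). The recovered shares therefore do not show that uncalled genes changed less than 2-fold.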

Results

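RNA-seq counts were obtained from CD8-negative dendritic cells sorted from mouse spleen, with 3 libraries from CpG-pretreated and 3 from untreated mice. CpG oligonucleotides are ligands of Toll-like receptor 9, and the series title describes the cells as paralysed after a systemic inflammatory syndrome. The comparison therefore addressed how the transcriptome of these dendritic cells differed after earlier exposure to CpG. Total counts were 7855500, 8048414 and 8228140 in untreated libraries 2, 3 and 4, and 8087299, 7989245 and 8111975 in CpG-pretreated libraries 2, 3 and 4.

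After CpG pretreatment, interferon-inducible genes and genes of red blood cell precursors showed the largest rises, and the matrix metalloproteinase genes Mmp9 and Mmp12 were among the largest falls. Iigp1, an interferon-inducible GTPase gene (Entrez 60440; GRCm38 chromosome 18, 60373616 to 60392634), rose from 0.785 ± 0.443 to 62.3 ± 51.4 CPM (SD, n = 3 per group), a log2 fold change of 6.29 (SE 0.92, edgeR adjusted p = 0.0388). Mmp9, which encodes a gelatinase (Entrez 17395; chromosome 2, 164940326 to 164955850), fell from 85.6 ± 27.5 to 11.1 ± 2.55 CPM, a log2 fold change of -2.95 (SE 0.26, adjusted p = 0.0146). The cell cycle list was higher and the red pulp macrophage list lower by the camera test with a preset correlation (adjusted p = 8.14e-20 and 9.08e-14), and neither was called with an estimated correlation (adjusted p = 0.593 for each).

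By edgeR's quasi-likelihood test, 113 of 11602 genes changed, 55 higher and 58 lower in CpG-pretreated cells. With the replicate number as a block, 988 genes changed, 549 higher and 439 lower, and 106 of the 113 were called in the same direction. Of the 113, 36 were higher and 37 lower by more than 2-fold, and of the 988 called with the block 104 and 115. In all 113 the libraries of both groups did not overlap, as in 18.7% of all genes tested, where chance gives 10%. The count depended on which libraries were kept, with fewer samples in each of the following fits. Without CpG-pretreated replicate 2 or 3 it was 0 (1065 and 1107 genes at an unadjusted p under 0.05 by edgeR, no other tool having been run on those subsets), without untreated replicate 3 it was 2 (Mmp9 and H2-M2), without untreated replicate 4 it was 1 (Mmp9), without untreated replicate 2 it was 34, and without CpG-pretreated replicate 4 it was 386.

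The 8 largest rises under the naming rule were those of Iigp1, Apol11b, Trim10, Ly6a, Alas2, Hbb-bs, Hba-a2 and Hbb-b1. Apol11b, an apolipoprotein L family gene, rose by a log2 fold change of 5.86 (SE 0.90, adjusted p = 0.0398), from 1.20 ± 0.816 to 70.1 ± 49.8 CPM. Ly6a, which encodes the surface protein Sca-1, rose by 4.29 (SE 0.59, adjusted p = 0.0379), from 5.32 ± 1.30 to 104 ± 66.6 CPM. Trim10, a gene of erythroid differentiation, rose by 4.38 (SE 0.68, adjusted p = 0.0398). Iigp1, Apol11b and Ly6a belong to families with similar copies, so which copy the counts came from is uncertain. In each of these 4 genes CpG-pretreated replicate 4 was the lowest of its group, at 14.5 CPM for Iigp1, 13.1 for Apol11b, 31.5 for Ly6a and 8.19 for Trim10. It was still above every untreated library, which the naming rule requires. All 8 lost their calls without a filter on low counts (adjusted p from 0.131 for Trim10 to 0.256 for Alas2) and by limma-voom (adjusted p from 0.0760 for Hbb-bs to 0.235 for Apol11b), with Iigp1 at 0.166 and 0.194 and Ly6a at 0.144 and 0.103. Alas2 also lost its call with library size only (adjusted p = 0.0558), upper quartile scaling (0.0511) and the filter at 1 CPM (0.0517).

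The 8 largest falls were those of Serpinb2, Mmp9, Spats2, Mmp12, Hpgd, H2-M2, Kcnj16 and Meis3, with log2 fold changes of -2.98, -2.95, -1.89, -1.85, -1.84, -1.83, -1.77 and -1.74. Serpinb2, an inhibitor of plasminogen activators, fell from 16.6 ± 4.02 to 2.08 ± 1.13 CPM (SE 0.35 on the log2 scale, adjusted p = 0.0236). Mmp12, macrophage elastase, fell from 205 ± 31.2 to 57.1 ± 22.9 CPM (SE 0.26, adjusted p = 0.0379). H2-M2, a non-classical MHC class I gene, fell from 101 ± 18.9 to 28.6 ± 5.68 CPM (SE 0.19, adjusted p = 0.0199), and Meis3, a homeobox gene, from 19.0 ± 1.01 to 5.67 ± 0.976 CPM (SE 0.17, adjusted p = 0.0146). All 8 were lower in each of the 3 pairs, which follows from the rule that groups do not overlap. They kept their calls with the block.

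**Figure D1:**
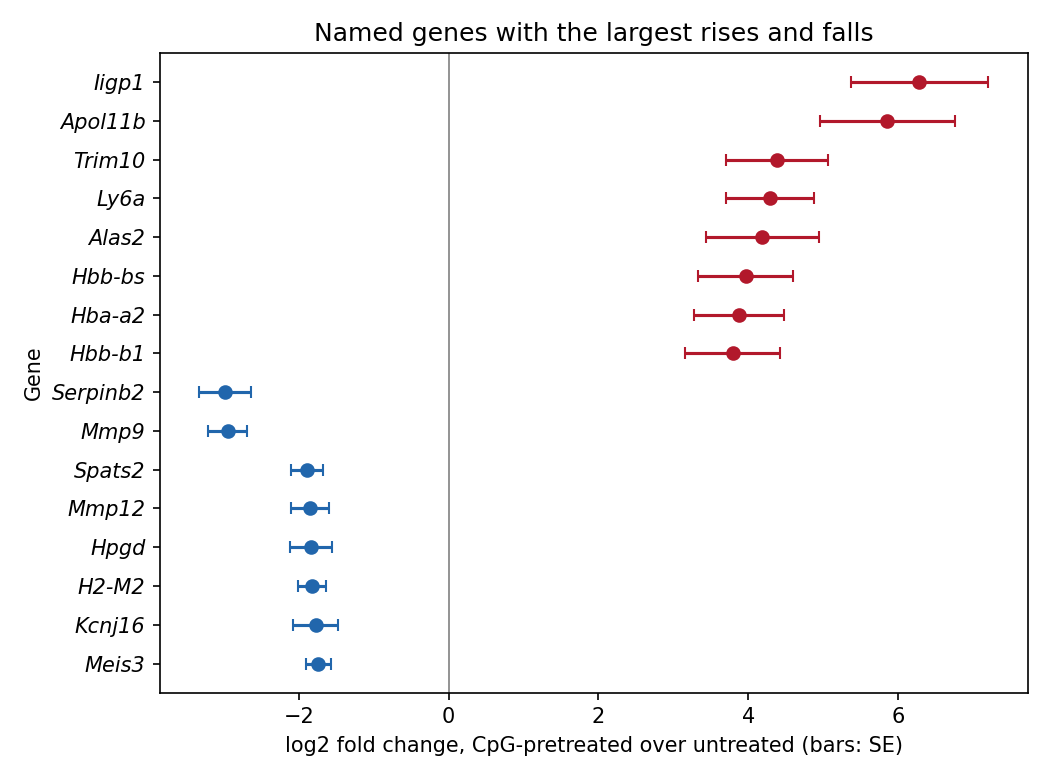
Log2 fold changes (x axis, CpG-pretreated over untreated, bars show the SE) of the 16 genes with the largest rises and falls under the naming rule (y axis). Rises run from 3.79 for Hbb-b1 to 6.29 for Iigp1, and falls from -1.74 for Meis3 to -2.98 for Serpinb2.

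Interferon-inducible genes were higher in CpG-pretreated cells. In the type I interferon response list 3 of 33 tested members rose, 11 when adjusted over the list alone and 12 with the block, and none fell. The rising members included Ifi44 (log2 fold change 3.02, SE 0.41, adjusted p = 0.0379) and Oasl1 (1.04, SE 0.15, adjusted p = 0.0388). The list median was 0.37 (camera adjusted p = 5.58e-13, and adjusted p = 0.593 with an estimated correlation). In the interferon-gamma response list 1 of 20 members rose, Iigp1, with 14 higher when adjusted over the list alone and 9 with the block. Its median was 0.81 (camera adjusted p = 4.10e-11, and adjusted p = 0.593 with an estimated correlation). Among its most abundant members, Serpina3g had a log2 fold change of 0.33 (adjusted p = 0.178, and 0.0131 with the block) and Ciita, the master regulator of MHC class II genes, 0.18 (adjusted p = 0.821). Medians of the interferon-gamma list were 0.95, 1.25 and 0.33 in pairs 2, 3 and 4. Erythroid transcripts (the erythroid list without Tfrc) moved with these genes, at 1641, 1503 and 372 CPM in CpG-pretreated libraries 2, 3 and 4 against 74.2, 176 and 70.4 CPM in untreated ones. With this erythroid signal as a covariate, chosen after the data were seen and correlated with the groups at 0.898, the type I list was not called (adjusted p = 0.0859) and the interferon-gamma list turned lower without a call (adjusted p = 0.945). A covariate this close to the groups leaves little of the contrast (0 genes called by edgeR). Here and below it cannot decide whether a list change depends on erythroid cells.

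Antigen presentation was covered by the MHC class I and class II lists, which were not tested against each other. In the MHC class I list 0 of 18 members passed the edgeR test over all genes, 4 were higher when adjusted over the list alone, and 9 rose with the block. The list median was 0.28 (camera adjusted p = 8.08e-07, and adjusted p = 0.593 with an estimated correlation), and it was 0.26, 0.43 and 0.15 in pairs 2, 3 and 4, lowest in the pair with the smallest erythroid signal. With the erythroid covariate, which is too close to the groups to tell a cause, the list was not called (adjusted p = 0.740). B2m, the light chain of class I molecules, had a log2 fold change of 0.27 (SE 0.11, adjusted p = 0.344, and 0.0222 with the block), and the heavy chain gene H2-K1 0.46 (SE 0.13, adjusted p = 0.169, and 0.00176 with the block). Tap1, a peptide transporter gene chosen after its values were seen, had 0.65 (adjusted p = 0.103, and 0.000766 with the block), and Nlrc5, a regulator of class I genes chosen in the same way, 0.92 (adjusted p = 0.0900, and 0.00145 with the block). In the MHC class II list 1 of 16 members fell, H2-Eb2 (log2 fold change -0.62, SE 0.10, adjusted p = 0.0434, and 0.0549 by limma-voom), and 1 was lower when adjusted over the list alone. The invariant chain gene Cd74 was at 22930 ± 2220 CPM in untreated and 21622 ± 2062 CPM in CpG-pretreated cells (-0.08, adjusted p = 0.863), and H2-Aa gave -0.07 (adjusted p = 0.915). The class II list was not called (camera adjusted p = 0.426), with a median of -0.07, a mean of 0.04 and a downward test.

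Cell division genes were higher in CpG-pretreated cells. In the cell cycle list 3 of 34 members rose, 24 when adjusted over the list alone and 31 with the block, and none fell. Top2a, a DNA topoisomerase gene, rose from 332 ± 11.5 to 542 ± 67.5 CPM (log2 fold change 0.71, SE 0.11, adjusted p = 0.0398), and the mitotic kinesin genes Kif11 and Kif20a rose by 0.68 (SE 0.11, adjusted p = 0.0398) and 0.64 (SE 0.11, adjusted p = 0.0444). Kif20a lost its call with library size only (adjusted p = 0.0629), upper quartile scaling (0.0729) and limma-voom (0.0615). List medians were 0.66, 0.50 and 0.47 in pairs 2, 3 and 4 and 0.57 over all libraries (camera adjusted p = 8.14e-20, and adjusted p = 0.593 with an estimated correlation). Erythroid transcripts moved with it (erythroid list median 3.87), and with the erythroid covariate the cell cycle median was 0.29 and its call held (camera adjusted p = 6.87e-05, and adjusted p = 0.972 with an estimated correlation).

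Red blood cell transcripts were higher in CpG-pretreated libraries. In the erythroid list 5 of 13 members rose, with 11 higher when adjusted over the list alone and 5 with the block, and none fell. The haem synthesis gene Alas2 rose by a log2 fold change of 4.19 (SE 0.75, adjusted p = 0.0485), Hbb-bs by 3.96 (SE 0.64, adjusted p = 0.0424), Hba-a2 by 3.87 (SE 0.60, adjusted p = 0.0398), Hbb-b1 by 3.79 (SE 0.63, adjusted p = 0.0435) and Bpgm by 2.04 (SE 0.34, adjusted p = 0.0427). With the block, Hba-a2 kept its call (adjusted p = 0.0466), while Alas2 (0.135), Hbb-bs (0.0668), Hbb-b1 (0.104) and Bpgm (0.0679) did not. Bpgm, like the other 4, also lost its call without a filter (adjusted p = 0.105) and by limma-voom (0.0732). The list median was 3.87 (camera adjusted p = 2.37e-11, and adjusted p = 0.593 with an estimated correlation). Globin genes are near-identical copies, and their counts may be split among them. Summed haemoglobin transcripts were at 22.5, 65.3 and 19.3 CPM in untreated and 730, 659 and 178 CPM in CpG-pretreated libraries 2, 3 and 4.

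Macrophage genes were lower in CpG-pretreated libraries. In the red pulp macrophage list 6 of 16 members fell, 14 when adjusted over the list alone and 13 with the block, and none rose. The complement genes C1qa and C1qc fell by 1.43 (SE 0.16, adjusted p = 0.0236) and 1.55 (SE 0.26, adjusted p = 0.0438) on the log2 scale, the prostaglandin-degrading enzyme gene Hpgd by 1.84 (SE 0.28, adjusted p = 0.0388) and Trf, encoding transferrin, by 1.07 (SE 0.16, adjusted p = 0.0388). C1qc was not called by limma-voom (adjusted p = 0.0615). List medians were -1.09, -1.32 and -1.28 in pairs 2, 3 and 4 (camera adjusted p = 9.08e-14, and adjusted p = 0.593 with an estimated correlation). The call held with the erythroid covariate (adjusted p = 1.34e-06, and adjusted p = 0.892 with an estimated correlation). With the block it was the 1 list that passed the fry rotation test (adjusted p = 0.0347). C1qa and C1qc were also the 2 members that fell among 16 in the Fc receptor and complement list, where 5 were lower when adjusted over the list alone (5 with the block). That list, with medians of -0.16, 0.05 and -0.50 in pairs 2, 3 and 4, was lower by camera (adjusted p = 0.0441, and adjusted p = 0.732 with an estimated correlation), and its call was lost with the block (adjusted p = 0.0684). It was also lost without untreated replicate 2 (0.0580) or 4 (0.168) and without CpG-pretreated replicate 2 (0.0874) or 4 (0.132), with upper quartile scaling (0.0531), without a filter (0.126), without genes shared between lists (0.993) and with the erythroid covariate (0.354). In the list of liver X receptor targets, Apoe fell by 1.32 (SE 0.12, adjusted p = 0.0146) and Pltp rose by 0.75 (SE 0.11, adjusted p = 0.0388), 2 called members of 15 (6 with the block). Adjusted over the list alone, 1 was higher and 2 were lower, and the list was not called (adjusted p = 0.582, a median of 0.004, a mean of -0.15 and a downward test).

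**Figure D2:**
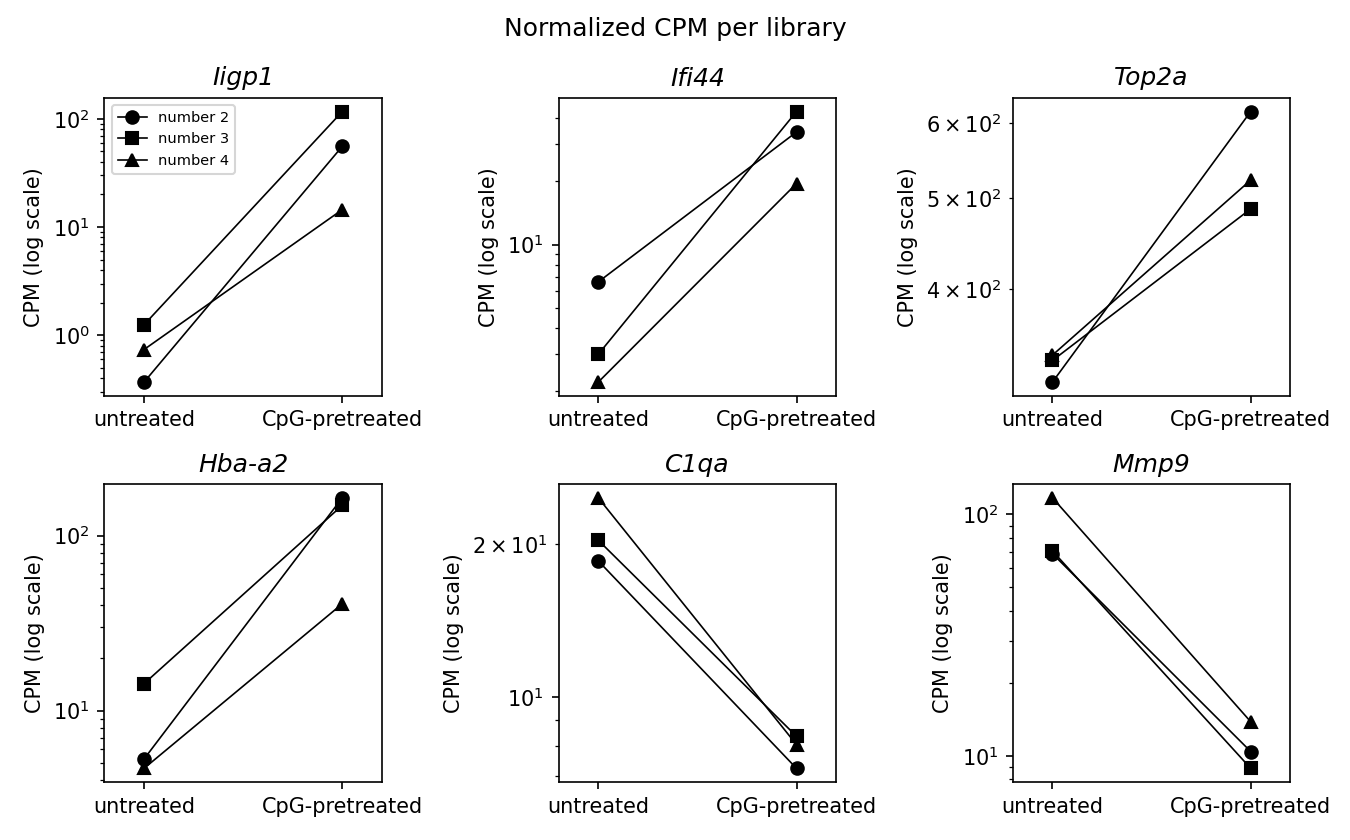
Normalized CPM on a log axis (y axis) of 6 genes in untreated and CpG-pretreated libraries (x axis), with 1 symbol per replicate number and lines joining equal numbers. Iigp1, Ifi44, Top2a and Hba-a2 were higher and C1qa and Mmp9 lower in every CpG-pretreated library.

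Markers of dendritic cell subsets were covered by several lists, which were not tested against one another. In the Notch2-dependent Esam-high cDC2 list 1 of 15 members fell, Esam (log2 fold change -0.75, SE 0.13, adjusted p = 0.0444, and 0.0615 by limma-voom), with 5 lower and 1 higher when adjusted over the list alone and 8 called with the block. Its abundant members Adgre5 and Tmem176b had -0.26 (adjusted p = 0.354, and 0.0425 with the block) and -0.28 (adjusted p = 0.514, and 0.0463 with the block). The list was lower (camera adjusted p = 0.00215, and adjusted p = 0.593 with an estimated correlation). It was not called without genes shared between lists (adjusted p = 0.0851), and with the erythroid covariate it turned higher without a call (adjusted p = 0.945). In the wider cDC2 list Esam was the only called member of 17 (6 with the block), with 1 higher and 3 lower when adjusted over the list alone. Its members Sirpa (-0.07, adjusted p = 0.917) and Dtx1 (-0.46, adjusted p = 0.146, and 0.00226 with the block) were not called, nor was the list (adjusted p = 0.124). In the cDC1 list 0 of 18 members passed the edgeR test, 8 were higher when adjusted over the list alone and 5 rose with the block. The list was higher (camera adjusted p = 0.00442, and adjusted p = 0.732 with an estimated correlation), with medians of 0.91, 0.67 and -0.06 in pairs 2, 3 and 4, and lost its call without CpG-pretreated replicate 3 (adjusted p = 0.0641). These medians were lowest in pair 4, where erythroid transcripts stood at 372 CPM against 1641 and 1503. Medians of the interferon-gamma list were lowest there too (0.95, 1.25 and 0.33 in pairs 2, 3 and 4). With the erythroid covariate the cDC1 list turned direction and was called lower (camera adjusted p = 0.0318, and adjusted p = 0.972 with an estimated correlation). The covariate correlated with the groups at 0.898, so this turn does not show that the cDC1 change depends on erythroid cells. Abundant members of the cDC1 list, Wdfy4 and Ppt1, gave -0.05 (adjusted p = 0.969) and 0.08 (adjusted p = 0.850). The largest rise in that list was that of Ifi205 (3.26, edgeR adjusted p = 0.0733). Ifi205 belongs to the interferon-inducible Ifi200 family and was chosen after its values were seen. Of the 18 members 13 had a log2 fold change above 0. How far the list's rise rests on interferon-inducible members was not tested. The cDC1 receptor gene Xcr1 was at 3.92 ± 0.660 and 9.48 ± 4.97 CPM (1.27, adjusted p = 0.185, and 0.00474 with the block), and Cd8a, against which the cells were sorted, at 2.48 ± 1.49 and 3.58 ± 1.69 CPM (0.53, adjusted p = 0.782). The pDC list was higher (0 of 11 members called, 1 when adjusted over the list alone, 1 with the block, camera adjusted p = 0.00282, and adjusted p = 0.593 with an estimated correlation), with Spib at 0.25 (adjusted p = 0.474) and Tcf4 at -0.01 (adjusted p = 0.983). The pDC list had medians of 0.41, 0.41 and -0.02 in pairs 2, 3 and 4 and was not called with the erythroid covariate (adjusted p = 0.651). In the cDC core list 1 of 13 members fell, the metalloproteinase gene Adam19 (-1.01, SE 0.15, adjusted p = 0.0388), also 1 when adjusted over the list alone, and 2 were called with the block. Itgax, encoding CD11c, gave -0.16 (adjusted p = 0.582), Dpp4 -0.08 (adjusted p = 0.864) and Flt3 0.04 (adjusted p = 0.954). The core list was not called (adjusted p = 0.750, a median of 0.02, a mean of -0.08 and a downward test). In the DC transcription factor list 1 of 30 members passed the edgeR test (2 when adjusted over the list alone, 4 with the block), and the list was not called (adjusted p = 0.730, a median of -0.02 and an upward test). Its most abundant members Ikzf1 and Spi1 had log2 fold changes of 0.07 and 0.03 (adjusted p = 0.934 and 0.955).

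Genes of dendritic cell activation were mostly outside the calls. The costimulation list (0 of 17 members called, 0 when adjusted over the list alone, 1 lower with the block) was lower by camera (adjusted p = 0.0441, and adjusted p = 0.732 with an estimated correlation), with Icosl at -0.05 (adjusted p = 0.933) and Traf1 at -0.10 (adjusted p = 0.813). Its medians were -0.26, 0.07 and -0.25 in pairs 2, 3 and 4. This list call ended without untreated replicate 2 (adjusted p = 0.280) and without CpG-pretreated replicate 2 (0.203) or 4 (0.216), and also without genes shared between lists (0.272). The migratory mature DC list was lower (adjusted p = 0.00909, and adjusted p = 0.787 with an estimated correlation), with 0 of 14 members called, 1 higher and 2 lower when adjusted over the list alone and 4 called with the block. Tmem123 gave -0.16 (adjusted p = 0.669) and Fscn1, an actin-bundling gene of mature dendritic cells, -0.28 (adjusted p = 0.601), and pair medians were -0.53, 0.18 and -0.50. Without untreated replicate 2 the migratory list had an adjusted p of 0.0580, and without CpG-pretreated replicate 2 or 4 one of 0.0874 or 0.229. The list of C-type lectins and scavenger receptors was lower (adjusted p = 0.0242, and adjusted p = 0.593 with an estimated correlation), with 0 of 21 members called, 5 lower when adjusted over the list alone and, with the block, 7 lower and 1 higher. Cd209a, a DC-SIGN homologue with close paralogs, gave -0.68 (adjusted p = 0.0885, and 0.000301 with the block) and Clec4a1 -0.12 (adjusted p = 0.810). The lectin list was not called without untreated replicate 4 (adjusted p = 0.0532) or without CpG-pretreated replicate 3 (0.0663) or 4 (0.102), without genes shared between lists (0.157) or with the erythroid covariate (0.0548). The list of Toll-like receptors and their signalling was not called (0 of 30 members, 0 when adjusted over the list alone, 3 with the block, camera adjusted p = 0.918, a median of -0.03 and an upward test). Tlr9, the CpG receptor gene, was at 199 ± 45.9 and 211 ± 49.4 CPM (0.08, adjusted p = 0.944), Unc93b1 gave -0.04 (adjusted p = 0.940) and Irf5 -0.09 (adjusted p = 0.787).

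Of the lists of metabolism and protein synthesis, glycolysis and cholesterol synthesis were higher by camera with no member called. Glycolysis had a median of 0.16 (0 of 20 members called, 2 higher and 1 lower when adjusted over the list alone, 2 with the block, camera adjusted p = 0.0186, and adjusted p = 0.665 with an estimated correlation), with Pfkfb3 at 0.03 (adjusted p = 0.967) and Pkm at 0.14 (adjusted p = 0.675). The glycolysis call ended without untreated replicate 3 (adjusted p = 0.113) or CpG-pretreated replicate 2 (0.0874), and with the erythroid covariate (0.671). Cholesterol synthesis and uptake had a median of 0.13 (0 of 21 called, 0 when adjusted over the list alone, camera adjusted p = 0.00743, and adjusted p = 0.732 with an estimated correlation), with Srebf2 at 0.09 (adjusted p = 0.890). The cholesterol call ended without untreated replicate 2 (adjusted p = 0.267) or CpG-pretreated replicate 3 (0.136), and with the erythroid covariate the list turned lower without a call (0.739). The ribosomal protein list was called only with the block (camera adjusted p = 0.164, and 0.0388 lower with the block, with adjusted p = 0.764 for the block with an estimated correlation), with 0 of 39 members called, 0 when adjusted over the list alone and 1 lower with the block. Rpl4 gave 0.03 (adjusted p = 0.959) and Rpl8 0.01 (adjusted p = 0.992), and both signs turned under other scalings.

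**Figure D3:**
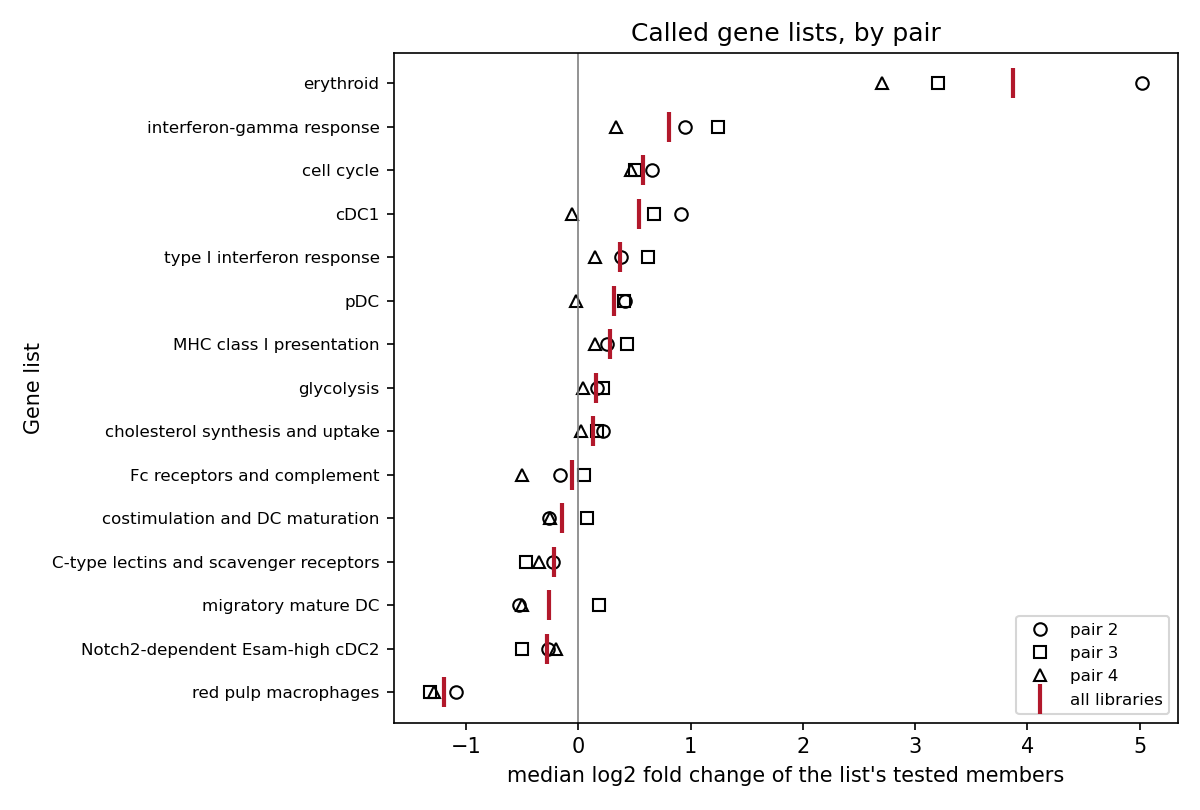
Median log2 fold change of tested members (x axis) of the 15 gene lists called without the block (y axis), for each of pairs 2, 3 and 4 and for all libraries. The erythroid list has the highest median, 3.87, and the red pulp macrophage list the lowest, -1.20.

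Markers of other blood and tissue cells gave few calls. In the monocyte list 2 of 21 members rose, Ly6a and the receptor gene Cd300e (1.23, SE 0.22, adjusted p = 0.0491, and 0.0558 with library size only, 0.0545 with upper quartile scaling and 0.0732 by limma-voom), with 5 higher and 5 lower both when adjusted over the list alone and with the block, and the list was not called (adjusted p = 0.461). Klrk1, encoding the receptor NKG2D, rose by 1.28 (SE 0.18, adjusted p = 0.0379) as 1 of 7 NK cell list members, also 1 when adjusted over the list alone. Ccl5 and Klrd1 gave -0.25 (adjusted p = 0.671) and -0.24 (adjusted p = 0.613), and the list was not called (adjusted p = 0.347). Tcf7 fell by 0.68 (SE 0.12, adjusted p = 0.0438, and 0.0568 by limma-voom) among 3 tested T cell list members, also 1 when adjusted over the list alone, with Cd5 at 0.02 (adjusted p = 0.975) and Il7r at -0.04 (adjusted p = 0.970), too few for a list test. In the list of stroma and endothelium Vwf fell by 0.85 (SE 0.13, adjusted p = 0.0388) and Kdr rose by 1.55 (SE 0.26, adjusted p = 0.0438, 0.0720 with the block and 0.0732 by limma-voom, each of which ended its call), 2 of 7 members, also 2 when adjusted over the list alone, with no list call (adjusted p = 0.262). In the neutrophil list Mmp9 was the 1 called member of 12, also 1 when adjusted over the list alone (2 called with the block), with Csf3r at -0.34 (adjusted p = 0.319) and Ngp at 1.26 (adjusted p = 0.558). The neutrophil list was called only with the block (higher, adjusted p = 0.0367, against 0.164 without it), as was the plasma cell list (higher, adjusted p = 0.0388, against 0.273), which had 0 of 14 members called, 0 when adjusted over the list alone and 4 higher with the block. With the block and an estimated correlation neither was called (adjusted p = 0.711 for each). Irf4 and Xbp1 gave -0.35 (adjusted p = 0.338) and -0.07 (adjusted p = 0.934). Immunoglobulin transcripts summed to 840, 854 and 637 CPM in untreated and 1873, 1047 and 724 CPM in CpG-pretreated libraries 2, 3 and 4.

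The other 17 lists tested had no called member without the block and camera adjusted p-values from 0.103 to 0.918. With the block 16 of them had called members, at most 6 in a list, which made 43 different genes in all. They covered inhibitory receptors, negative regulators of inflammatory signalling, inflammatory cytokines, chemokines, lysosome, NADPH oxidase, oxidative phosphorylation, the unfolded protein response, immediate early genes, glucocorticoid response, TGF-beta response, vesicle traffic, migration in the spleen, growth factor receptors, Clec12a-positive cDC2, B cells and progenitors. The median and the camera direction differed in sign for chemokines, vesicle traffic and Clec12a-positive cDC2. The lists of platelets and of basophils, mast cells and eosinophils had fewer than 5 tested members and no called member without the block. With the block each had 1 lower member, both chosen after their values were seen. These were Clec1b, with a log2 fold change of -1.49 (adjusted p = 0.146, and 0.0294 with the block), and Ccr3, with -2.49 (adjusted p = 0.0848, and 0.00571 with the block). With an estimated correlation no list was called, with or without the block (lowest adjusted p = 0.533 with it and 0.593 without).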

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

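Blocked fits in DESeq2 and limma-voom or without 1 pair, the block with an estimated correlation or fry, and the erythroid covariate were chosen after the data were seen. The count of changed genes (113, with 55 higher and 58 lower) stayed within 1.5 times, at 107 to 113, under the other normalizations, the filter at 1 CPM, the non-robust fit and without immunoglobulin, T cell receptor and haemoglobin genes. It was 189 (98 higher, 91 lower) without a filter, which tested more genes, 439 (279 and 160) by the DESeq2 Wald test, 41 (14 and 27) by limma-voom and 1 (0 and 1, Mmp9) against a 1.5-fold change, a stricter question. With the replicate block it was 988 (549 higher, 439 lower), with the block in DESeq2 493 (312 and 181) and in limma-voom 989 (554 and 435). With the block and without pair 2 it was 513 (264 and 249), without pair 3 482 (256 and 226) and without pair 4 1594 (940 and 654). With the erythroid covariate it was 0 (0 and 0, with 199 genes at an unadjusted p under 0.05 by edgeR). Leaving out 1 library gave 0 to 386 genes, 0 to 275 higher and 0 to 111 lower, with fewer samples in each fit. Beyond the calls given in the report with their blocked values, the block changed no other call of a named gene or described list. For the other moves the cause was not tested.

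Of the 15 list calls (9 higher, 6 lower), 0 and 0 held with an estimated correlation, 0 and 0 with fry, and 0 and 0 with the block and an estimated correlation (3, 8 and 1 of 44 lists at an unadjusted p under 0.05). With the block fry called 0 higher and 1 lower, red pulp macrophages (adjusted p = 0.0347). Without genes shared between lists 9 were higher and 2 lower, with 4 calls lost, as given in the report. Leaving out 1 library gave 7 to 12 lists higher and 4 to 7 lower. With the erythroid covariate 2 were higher and 6 lower, and 4 of the 15 calls held in the same direction (costimulation, cell cycle, migratory mature DC and red pulp macrophages). There the interferon-gamma (adjusted p = 0.945), cholesterol (0.739), cDC1 (0.0318) and Esam-high cDC2 (0.945) lists turned direction. With the covariate and an estimated correlation 0 were higher and 0 lower (0 at an unadjusted p under 0.05), and those 4 turned as well (adjusted p = 0.984, 0.972, 0.972 and 0.984). The erythroid list supplies the covariate, so its values there (adjusted p = 0.153 and 0.892) test nothing. The covariate correlated with the groups at 0.898. The choice of gene test leaves camera as it is.

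Uncalled genes near 0 turned sign under a scaling: Rpl4 to -0.0018 with upper quartile, Rpl8 to -0.017 with library size only and -0.030 with upper quartile, Spi1 to -0.0035 with upper quartile, and Cd5 to -0.0037 with library size only and -0.015 with upper quartile. Leaving out 1 library turned others, with these lowest and highest log2 fold changes: Cd74 -0.14 to 0.0087, H2-Aa -0.13 to 0.045, Icosl -0.11 to 0.014, Unc93b1 -0.055 to 0.0066, Pfkfb3 -0.089 to 0.12, Srebf2 -0.019 to 0.17, Rpl4 -0.028 to 0.11, Rpl8 -0.087 to 0.17, Ikzf1 -0.054 to 0.17, Spi1 -0.0082 to 0.10, Dpp4 -0.15 to 0.0013, Wdfy4 -0.26 to 0.091, Tcf4 -0.11 to 0.047, Xbp1 -0.18 to 0.030, Cd5 -0.024 to 0.052, Il7r -0.20 to 0.12, Tlr9 -0.082 to 0.27, Flt3 -0.064 to 0.11 and Aim2 -0.064 to 0.027. With 1 count worth about 0.123 CPM, genes below the filter were not tested.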

Other observations

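The tests of globin paralogs, of the erythroid covariate and of the library CpG-pretreated 4 were chosen only after the results were seen. So were the gene families described next and the list of further erythroid genes. In the Ifi200 family, a cluster of interferon-inducible DNA sensor genes, 4 of 11 tested members rose, and 6 with the block. Ifi203 rose by a log2 fold change of 0.99 (SE 0.13, edgeR adjusted p = 0.0379), Ifi211 by 1.85 (SE 0.27, adjusted p = 0.0388) and Ifi213 by 1.02 (SE 0.17, adjusted p = 0.0434). Mndal rose from 89.5 ± 6.70 to 179 ± 29.9 CPM (SD, adjusted p = 0.0379), while Aim2 gave -0.02 (adjusted p = 0.973). Of 4 Ly6 genes Ly6a and Ly6i rose, the latter by 2.62 (SE 0.33, adjusted p = 0.0327). Among 10 non-classical MHC class I genes H2-Q7 rose by 1.17 (SE 0.19, adjusted p = 0.0427) and H2-M2 fell by 1.83 (SE 0.19, adjusted p = 0.0199), with 6 higher and 1 lower with the block. Among 13 matrix metalloproteinase and ADAM genes Mmp9, Mmp12, Adam19 and Adamdec1 fell, the last by 1.84 (SE 0.21, adjusted p = 0.0236), and with the block 6 were lower and 1 higher, Adam11 (0.52, adjusted p = 0.0828, and 0.000866 with the block). By limma-voom Ifi211 (adjusted p = 0.0514), Ifi213 (0.0615, and 0.0516 with upper quartile scaling), Ly6i (0.0549) and H2-Q7 (0.0568) were not called. The Ifi200, Ly6 and H2-Q members are close copies of one another, so single members are uncertain.

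Libraries numbered 2 stood apart by gene length. Across genes, which are not independent replicates, deviations from the group mean of log2 CPM had Spearman correlations with gene length of -0.67 in untreated 2 and -0.55 in CpG-pretreated 2, against 0.53, 0.50, 0.23 and 0.39 in untreated 3, untreated 4, CpG-pretreated 3 and CpG-pretreated 4. On the first principal component (46.7% of the variance) CpG-pretreated 4 lay at 2.47, between the untreated libraries (-23.7 to -17.1) and CpG-pretreated 2 and 3 (30.6 and 26.9).

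Of the 10 splits of the 6 libraries into 3 and 3, only the real one (1) gave 113 changed genes, and the highest of the others gave 0. With the block, of the 4 splits that part all 3 pairs only the real one (1) gave 988, and the highest other gave 0. With so few splits no share under 0.05 can be had.

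Erythroid transcripts were higher in CpG-pretreated libraries although the cells were sorted as dendritic cells. Reads shared between globin copies are argued against as the whole cause, since the 10 list members that are not globins had a median log2 fold change of 3.76, with 9 above 0.5. The list median of 3.87, known before, left this test little room to come out otherwise. Erythroid cells or their RNA carried through the sort may be a source. A list of further erythroid genes, of which 10 were tested, was written after the data were seen. Of the 10, 60% were higher in all 3 pairs (median log2 fold change 1.99). This lay between bounds of 80% and 50% set before these genes were looked at. Of the 4 others 3 exceeded 10 CPM in untreated libraries, where a small carried-over share would not show. Carried-over cells or RNA therefore cannot be told apart from transcription in the sorted cells. None of the 13 tested list genes is held by another list, 12 averaged above 1 CPM in untreated libraries, and in CpG-pretreated libraries Tfrc averaged 260 CPM (288 in untreated), Alas2 208, Hbb-b1 207 and Hbb-bs 198. An effect of CpG on the dendritic cells themselves was not tested separately.

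Cell cycle genes could also come from dividing erythroid precursors. With the erythroid signal as a covariate the list's median log2 fold change went from 0.57 (interquartile range 0.28) to 0.29 (0.46), above the bound of 0.1 and below that of 0.3, and the list kept its camera call (adjusted p = 6.87e-05) but passed neither camera with an estimated correlation (adjusted p = 0.972) nor the fry rotation test at 0.05. The interferon-gamma median went from 0.81 to -0.08, and the red pulp macrophage median from -1.20 to -1.05. The covariate correlated with the groups at 0.898 over 6 libraries, so erythroid precursors cannot be told apart from division of dendritic cells here. In pair 4, with the smallest erythroid signal, the cell cycle median was 0.47 against 0.66 and 0.50.

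Interferon-gamma genes were less raised in CpG-pretreated 4. Untreated cells mixed into that library would take the same part off every change on the linear scale, but the change in pair 4 (fold minus 1, from list medians) as a share of that in pairs 2 and 3 was 0.226 for the interferon-gamma, 0.776 for the cell cycle and 1.04 for the red pulp macrophage list. The interferon-gamma share was lower than the others by differences of -0.550 (95% bootstrap interval over genes -0.808 to -0.349, 10000 draws, taking correlated members as independent) and -0.816 (-1.16 to -0.523), and by -0.391 to -0.833 against pair 2 or 3 alone. The intervals cover spread over genes for this 1 library and no spread between samples. Apart from that spread, the unequal shares argue against such a mixture as the whole cause. Lower depth is argued against too, since the larger of the other CpG-pretreated totals was 0.997 times its own. The smaller change was not particular to interferon genes. Erythroid transcripts stood at 372 CPM in CpG-pretreated 4 against 1641 and 1503 in CpG-pretreated 2 and 3. Medians in pairs 2, 3 and 4 were 0.91, 0.67 and -0.06 for the cDC1 list and 0.41, 0.41 and -0.02 for the pDC list. A candidate explanation left open is that CpG-pretreated 4 was exposed differently or collected at another stage of the interferon response, which was not tested.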
